A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

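The series measured where the budding yeast proteins Abf1 and Reb1 sit on the genome. Each protein carried a TAP tag (a tandem affinity purification tag, bound here by immunoglobulin G on agarose) in its own strain. Per the labels' protocols, cells growing logarithmically in rich YPD medium at 30 °C were fixed with formaldehyde, broken with glass beads and sonicated, and the chromatin bound to the tagged protein was purified. Libraries were made with a low-input kit from the ChIP DNA and from input chromatin of the same strain. The 4 libraries form 4 groups of 1: Abf1 ChIP, Abf1-strain input, Reb1 ChIP and Reb1-strain input.

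The deposited read files list aligned reads by chromosome, start, end and strand. Per the submitters' processing notes, reads were aligned with Bowtie to the sacCer3 build; the Bowtie version and settings are not given in the sources used here. In the files, every read was 50 bases long and each library came from 1 sequencing lane. The score that the authors deposited beside each read was 255 in every line and was not used. Reads fell on 16 nuclear chromosomes and the mitochondrial genome. The deposited peak lists, 1 per ChIP sample, give only chromosome, start and end, with no height, fold or p-value. Starts end in 1 and ends in 0, so the regions lie on a 10 bp grid and were read as 1-based inclusive positions. The peak caller, its threshold and the control it used are not given in the sources used here.

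Gene positions and symbols came from a RefSeq gene table of the R64 assembly, the assembly that sacCer3 is named for, and strand was taken from the systematic name. Of its 6002 nuclear coding genes, 96.4% have a length that is a multiple of 3, so gene ends are coding ends and no untranslated regions were used. No genome sequence was used here, so the motif results planned before the data were examined were not computed. Replication origins, telomeric elements, long terminal repeats and centromeres were not analysed here, because the gene table does not list them.

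Reads were reduced to their 5' ends and moved towards the fragment middle by a shift estimated from each ChIP library. The lag between the strands with the highest correlation, searched from 100 to 600 bp in steps of 10 bp with at most 50 reads per position, was 390 bp for Abf1 and 260 bp for Reb1. The shifts were therefore 195 bp and 130 bp, and each input was shifted like its ChIP. Counts in a region were divided by the library's nuclear reads outside the ribosomal DNA (chromosome XII, 450575 to 490469). ChIP over input was the ratio of these values with a pseudocount of 1 read added to each count in log2 values; folds of single named peaks and regions were computed without a pseudocount. Under this scaling the median 1 kb bin outside peaks lay at a log2 value of -0.60 for Abf1 and -0.73 for Reb1, since peaks take up a large share of the ChIP reads. Values below 0 are therefore to be read against that level. A second count kept 1 read per position and strand. It cannot rise once positions are filled, so it understates folds at the strongest sites and says nothing about the spacer of the ribosomal DNA, where ChIP and input filled similar shares of positions. Features without input reads were left out of the feature medians.

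Depth ranged from 9952630 reads (Reb1 ChIP) to 15026246 reads (Abf1-strain input). The groups hold 1 library each, so no test between conditions was made and no p-value across genes or peaks is given. Medians carry distribution-free 95% intervals over peaks or features, shares carry exact (Clopper-Pearson) binomial 95% intervals, and folds of single regions carry exact conditional binomial 95% intervals. All intervals cover counting error or the spread over regions within these libraries only. Reads had no molecular identifiers, so copies of a molecule are not independent and the counting intervals are too narrow.

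A promoter was the 500 bp upstream of a start codon, and a peak was placed by its centre. Peaks of the factors were called shared when they overlapped by at least 1 bp. Observed overlap stands beside 1000 placements of the Reb1 peaks with centres at random in sequence outside coding regions, and peak locations beside 1000 random placements over all 1 kb bins that held input reads. Fixed before the data were examined were 14 gene lists, of which 687 of 688 names were found in the gene table. For each list the number of promoters with a peak was set beside 10000 random lists of the same size, in 28 comparisons. The numbers of random lists given were not corrected for the number of comparisons or of alternative rules. The same was done with random lists matched on 5 classes of upstream intergenic length. Random means and list counts given below are those of unmatched lists unless matched lists are named. The lists were ribosomal proteins, ribosomal protein genes known for an Abf1 site, ribosome biogenesis, RNA polymerases I and III, mitochondrial ribosomal proteins, proteasome, glycolysis, respiratory chain, aminoacyl-tRNA synthetases, translation factors, general regulatory factors, DNA replication, galactose and phosphate genes, and stress response.

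Genes were named by a rule set before the data were examined. Per factor it takes the genes of the 10 peaks with the highest ChIP over input, which the rule prescribes where a peak list has no score, and up to 4 members of each list with the highest ChIP over input. It adds the 6 ribosomal protein genes with a known Abf1 site, the genes of the 5 shared peaks with the highest smaller ratio, and ABF1 and REB1. A gene belonged to a peak whose centre lay in its promoter. Other genes named are said to have been chosen after their values were seen.

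Alternatives planned before the data were examined covered scaling on the median 1 kb bin outside peaks, 1 read per position and strand, the input of the other strain, a pseudocount of 10 reads, unshifted reads, the stronger part of each peak list, stricter overlap rules, promoters of 300 or 1000 bp, 2-fold windows of 200 bp in place of peaks, and any base of a peak in a promoter. Added after the data were seen were joining of regions at most 500 bp apart, leaving out regions within 10 kb of a chromosome end, and the peak summit in place of the centre. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9. The functions were tested on simulated reads over 495 Abf1 regions of which 200 were enriched. For simulated folds of 2, 4 and 8 the median recovered folds were 1.974, 3.945 and 7.815. These were taken relative to the unenriched regions, unlike the folds reported below. The simulated reads were spread evenly, without repeated copies, and the regions were at least 200 bp wide. The simulation therefore does not show how repeated reads or narrow peaks affect the reported folds. The simulated fragment length of 300 bp was recovered as 300 bp at point-like sites and as 280 bp in evenly filled regions.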

Results

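Abf1 and Reb1 are general regulatory factors, abundant yeast proteins that bind specific DNA sites in many promoters. Their genomic positions were measured by ChIP-seq in strains that carry a TAP tag on either protein, with an input library from each strain. The files held 11070446 reads for the Abf1 ChIP, 15026246 for its input, 9952630 for the Reb1 ChIP and 14601062 for its input. The ChIP libraries were less complex than the inputs. Distinct positions made up 29.2% of the Abf1 ChIP reads and 11.2% of the Reb1 ChIP reads, against 64.3% and 68.6% in the inputs, and the median position in the Reb1 ChIP was read 7 times. There was 1 library per group, so no difference has a replicate check. The authors listed 936 Abf1 peaks (median width 240 bp, 529.0 kb in all) and 835 Reb1 peaks (median width 460 bp, 420.3 kb in all).

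The comparison of the Abf1 ChIP with its input asked where tagged Abf1 was enriched. Abf1 peaks held 31.2% of the nuclear Abf1 ChIP reads and 5.15% of the input reads. The strongest Abf1 peaks lay in promoters of genes of varied function. The highest ratio, 16.7-fold, was found at chromosome XIV, 56781 to 59060, between the start codons of the divergent genes MCK1 (YNL307C), which encodes a protein kinase, and MRPS18 (YNL306W), which encodes a mitochondrial ribosomal protein. It was followed by the promoter of EGD1 (YPL037C; chromosome XVI, 481151 to 483030; 15.7-fold), a subunit of the nascent polypeptide-associated complex. The promoter shared by SUI1 (YNL244C), a translation initiation factor, and SLA2 (YNL243W), an endocytic actin-binding protein, reached 14.9-fold at chromosome XIV, 186881 to 188850. Also among the 10 strongest were the promoters of KRE1 and VNX1 (14.8-fold), of TFA1, the large subunit of the general transcription factor TFIIE (14.8-fold), of YAP1801 and MPC2 (14.2-fold), of STE20 (13-fold) and of YGR054W (12.7-fold). The remaining 2 were not centred in a promoter. The region at chromosome XIV, 411661 to 414130 (14.8-fold), was centred in RPC19 and covered its start codon at 412771. The region at chromosome XI, 99061 to 100780 (13.2-fold), was centred outside coding sequence.

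Over all 936 Abf1 peaks the median Abf1 ChIP over input was 2.48-fold (95% interval 2.33 to 2.59), and 600 peaks (64.1%, 60.9% to 67.2%) were at least 2-fold above input. The Reb1 ChIP over its own input, the background for these regions, had a median of 0.824-fold (0.767 to 0.865) in the same peaks, a log2 value of -0.28 that became 0.45 when the median bin outside peaks was set to 1, and 186 of the 936 were at least 2-fold. Ratios rose with peak width. The 239 Abf1 peaks of 10 to 50 bp had a median of 1.56-fold and the 233 peaks of 1010 to 3190 bp a median of 6.99-fold. With 1 read per position and strand the median over all peaks was also 2.48-fold. The median coding sequence, however, rose from a log2 value of -0.56 to -0.25 on that count, so peaks stood less far above it. The 10 strongest peaks cannot be compared on that count: their ChIP reads already filled 58.4% to 68.9% of all positions and the input reads 39.8% to 49.8%, so no fold above 7.47 was possible.

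The same comparison was made for Reb1. Reb1 peaks held 38.4% of the nuclear Reb1 ChIP reads and 4.51% of the input reads. Of the 10 strongest, 7 lay within 10 kb of a chromosome end, led by chromosome VIII, 61 to 380 (89.0-fold), chromosome XII, 31 to 220 (72.8-fold), and chromosome XII, 5601 to 5940 (54.6-fold). These rest on few input reads, 47 in the strongest, and on repeated reads: with 1 read per position they were 30.0-fold (20.3 to 45.4), 11.6-fold (8.52 to 15.8) and 19.2-fold (15.6 to 23.8). Another, at chromosome XII, 489371 to 489930, lay next to the annotated ribosomal RNA genes (63.2-fold, and 15.5-fold with 1 read per position, where filled positions allowed at most 28.0-fold). The other 2 were promoters: that of TIM23 (YNR017W), a subunit of the mitochondrial inner membrane translocase, at chromosome XIV, 661921 to 663120 (28.6-fold), and that of VPS13 (YLL040C), a lipid transfer protein, at chromosome XII, 63161 to 64270 (28.2-fold). With 1 read per position these promoters were 8.92-fold and 10.1-fold over input, where filled positions allowed at most 17.3-fold and 21.5-fold.

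Over all 835 Reb1 peaks the median Reb1 ChIP over input was 5.63-fold (5.34 to 5.93), and 781 (93.5%, 91.6% to 95.1%) were at least 2-fold above input. The Abf1 ChIP over its own input had a median of 0.939-fold (0.904 to 0.971) there, a log2 value of -0.09 that became 0.51 with the median bin outside peaks set to 1, and 145 of the 835 were at least 2-fold. The 214 Reb1 peaks of 10 to 160 bp had a median of 3-fold and the 204 peaks of 810 to 2030 bp a median of 10.3-fold.

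**Figure D1:**
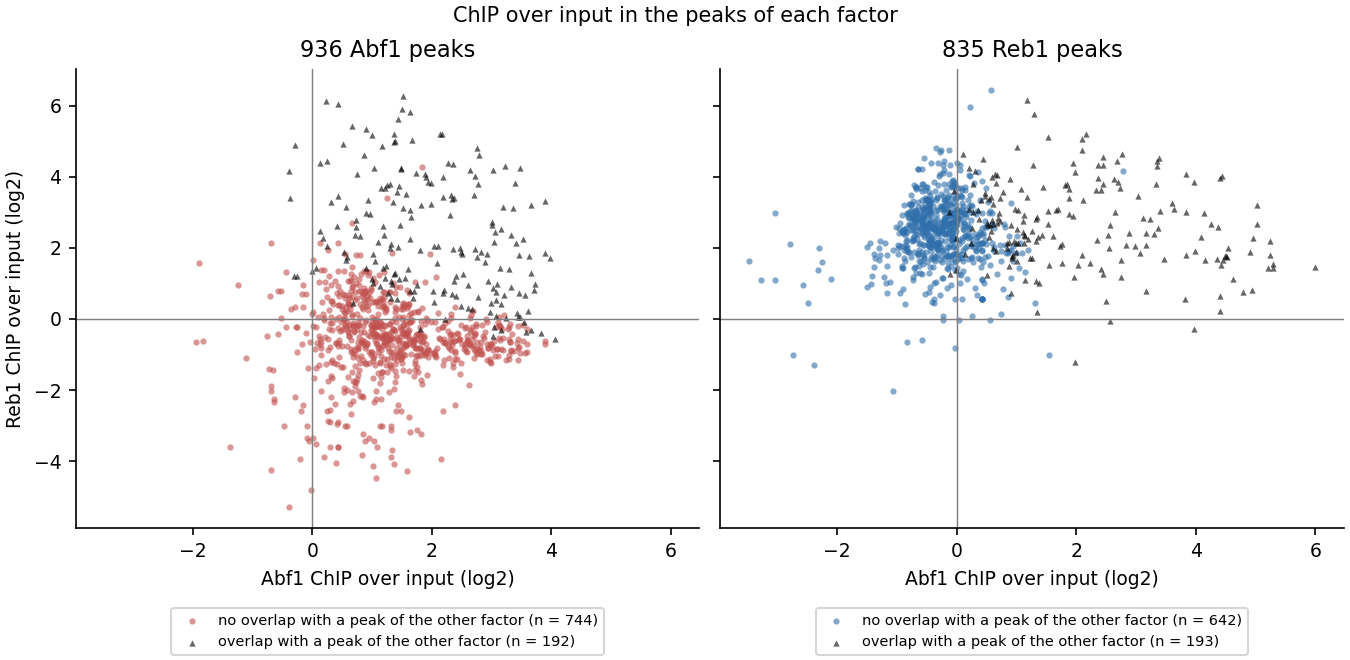
Abf1 ChIP over input (horizontal, log2) against Reb1 ChIP over input (vertical, log2) for each Abf1 peak (left, n = 936) and each Reb1 peak (right, n = 835). Triangles are the 192 Abf1 and 193 Reb1 peaks that overlap a peak of the other factor.

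**Figure D2:**
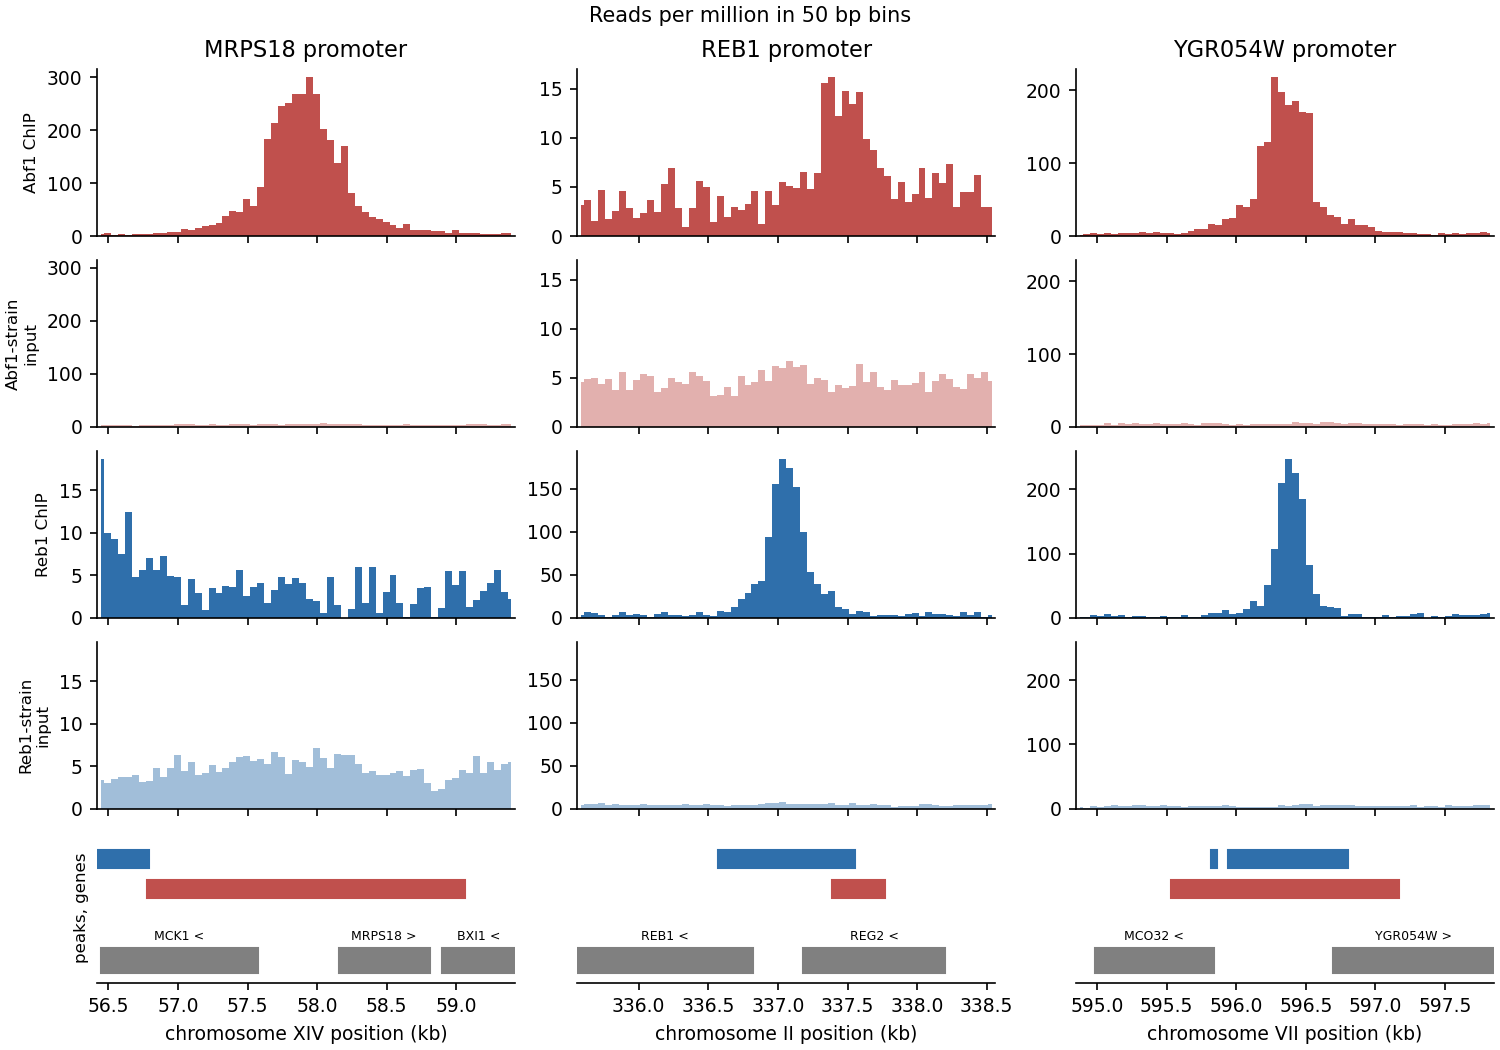
Depth-scaled reads in 50 bp bins for the 4 libraries (rows, each ChIP and its input on the same scale) at the promoters of MRPS18, REB1 and YGR054W (columns), with position in kb, peaks as coloured bars (blue Reb1, red Abf1) and genes in grey. Folds over the called peak are 16.7 for Abf1 at MRPS18 and 11.7 for Reb1 at REB1; over the Abf1 peak at YGR054W they are 12.7 for Abf1 and 9.19 for Reb1.

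The factors were next compared with each other. Of the Abf1 peaks, 192 (20.5%, 18.0% to 23.2%) overlapped a Reb1 peak, and 193 Reb1 peaks (23.1%, 20.3% to 26.1%) overlapped an Abf1 peak. Random placements of the Reb1 peaks outside coding sequence gave a mean of 111.4 overlapping Abf1 peaks, 95% of them between 90.98 and 134 and none above 142. The overlap was thus 1.72 times the random mean. The placements did not keep the preference of both factors for promoters and for sequence between divergent genes, described below. This ratio and the random means for stricter rules therefore cannot tell overlap due to that shared preference from overlap beyond it. The promoter of YGR054W, which encodes a translation initiation factor, showed 12.7-fold Abf1 and 9.19-fold Reb1 enrichment at chromosome VII, 595531 to 597170. The region centred in RPC19, which encodes a subunit common to RNA polymerases I and III, showed 14.8-fold and 9.99-fold. The region at chromosome XVI, 640771 to 642270, which was not centred in a promoter, showed 9.33-fold and 19.7-fold. The remaining 2 of the 5 strongest shared peaks were at chromosome ends: chromosome III, 315711 to 316310 (11.3-fold and 19.2-fold), and chromosome XI, 381 to 800 (10.6-fold and 14.3-fold). Only 55 Abf1 peaks met a stricter rule of overlap over at least 50% of both peaks (random mean 19.5), and 83 had a centre within 100 bp of a Reb1 centre (random mean 34.9).

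The location of the peaks relative to genes was then examined. Both factors lay mainly in promoters. Of the Abf1 peaks, 530 (56.6%, 53.4% to 59.8%) had their centre in a promoter and 234 (25.0%, 22.3% to 27.9%) in a coding sequence; random placement gave means of 16.3% and 72.7%. Of the Reb1 peaks, 598 (71.6%, 68.4% to 74.7%) were centred in a promoter and 123 (14.7%, 12.4% to 17.3%) in a coding sequence, against 16.2% and 72.8% at random. Peaks centred in coding sequence were narrower, with a median width of 110 bp for Abf1 and 80 bp for Reb1 against 335 bp and 525 bp in promoters. Their median log2 ChIP over input was 1.01 against 1.45 in promoters for Abf1, and 1.66 against 2.58 for Reb1. Among peaks between genes, 325 of 680 Abf1 peaks (47.8%, 44.0% to 51.6%) and 327 of 690 Reb1 peaks (47.4%, 43.6% to 51.2%) lay between divergent genes, where random placement gave 33.0% and 32.9%. Between convergent genes there were 41 Abf1 peaks (6.03%, random mean 16%) and 20 Reb1 peaks (2.90%, random mean 16.1%). Promoter peaks were centred a median of 196 bp (Abf1, quartiles 128.5 and 303) and 190.5 bp (Reb1, quartiles 143.5 and 272.8) upstream of the nearest start codon. A promoter of 300 bp lowered the Abf1 share to 41.9% and the Reb1 share to 58.3%. The intervals treat each listed region as independent, although many regions lay close together. Joining regions at most 500 bp apart left 654 Abf1 and 711 Reb1 loci. Their promoter shares were 65.9% and 75.5%, above the intervals given for the listed peaks.

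**Figure D3:**
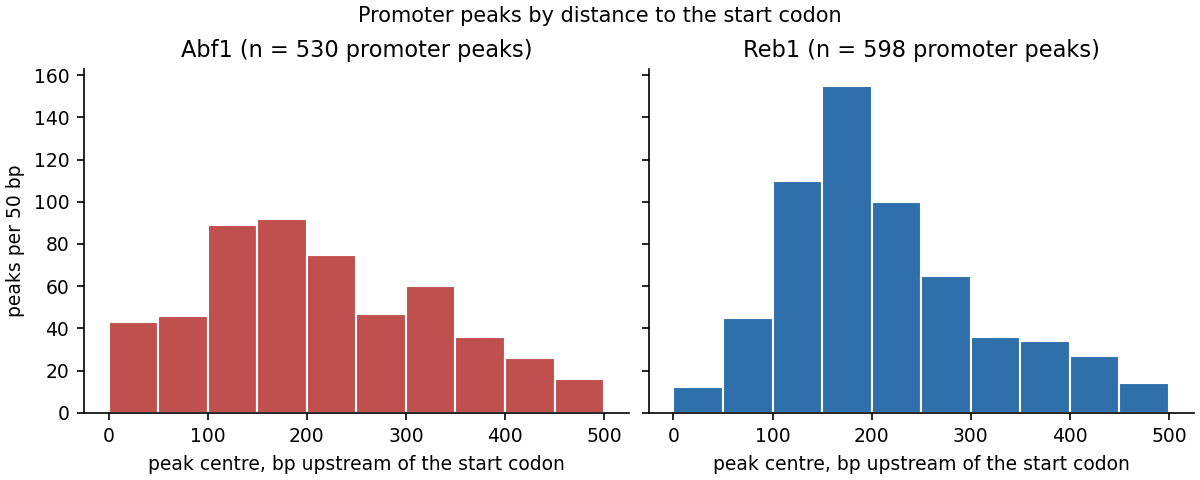
Number of promoter peaks (vertical) by distance of the peak centre upstream of the nearest start codon in 50 bp classes (horizontal, bp) for 530 Abf1 and 598 Reb1 peaks. The medians are 196 bp and 190.5 bp.

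The question of the study concerned promoters of genes for making ribosomes. In all, 670 of the 6002 nuclear coding genes (11.2%, 10.4% to 12%) had an Abf1 peak in their promoter and 776 (12.9%, 12.1% to 13.8%) had a Reb1 peak. Of 181 ribosome biogenesis genes, 40 had an Abf1 peak (22.1%, 16.3% to 28.9%), where random lists gave a mean of 20.2 and 1 of 10000 reached 40. The strongest were RIX7, an ATPase of large-subunit export (11.8-fold), SSF2 (11.5-fold), FCF1 (10.1-fold) and SOF1 (8.76-fold), all of which act in ribosomal RNA processing or subunit assembly. Reb1 peaks were found at 35 of the 181 (19.3%, 13.9% to 25.9%; random mean 23.4, reached by 87 of 10000 lists). This excess shrank with wider promoters: with 1000 bp the count was 38 against 30.2 by chance (750 of 10000 lists), and with any base of a peak in the promoter 38 against 28.4 (329 of 10000). Reb1 peaks were strongest at NIP7 (17.1-fold), KRI1 (14.1-fold), RRP14 (13.2-fold) and the RNA helicase gene HAS1 (13-fold).

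Ribosomal protein genes were compared with random lists in the same way; the difference from ribosome biogenesis genes was not tested. Of 137 ribosomal protein genes, 20 had an Abf1 peak (14.6%, 9.15% to 21.6%), within the range of random lists (mean 15.3, 1268 of 10000 reaching 20). Lists matched on upstream intergenic length averaged 17.9, with 3349 of 10000 reaching 20. Among peaks centred in the promoter of such a gene, the highest ratios were those of RPL35B (2.98-fold), RPL8B (2.87-fold), RPL43B (2.64-fold) and RPL3 (2.33-fold). Among the 468 Abf1 peaks with the highest ChIP over input, 3 of the 137 genes had a peak where random lists averaged 9.75 and 85 of 10000 had 3 or fewer, so the position of this list relative to chance depended on the weaker peaks. Reb1 peaks were found at 9 of the 137 (6.57%, 3.05% to 12.1%), where random lists averaged 17.8 and 107 of 10000 had 9 or fewer. Matched lists averaged 20.3, with 28 of 10000 at 9 or fewer. The genes with a Reb1 peak were RPL15B (13.4-fold), RPL40A (8.64-fold), RPL18B (8.32-fold), RPL41A (7.34-fold) and 5 others.

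The 6 ribosomal protein genes known for an Abf1 site in their promoter were examined singly. An Abf1 peak was centred in the promoters of RPP1A (YDL081C, 2.25-fold, 143 bp upstream), RPL3 (YOR063W, 2.33-fold, 161 bp upstream) and RPS28A (YOR167C, 2.25-fold, 153 bp upstream). The promoter of RPS28B (YLR264W) was 3.2-fold (2.93 to 3.49) above input and that of RPS22B (YLR367W) 4.52-fold (4.15 to 4.92). Both were touched by a wide Abf1 peak whose centre lay elsewhere, on chromosome XII from 672561 to 674070 (2.33-fold) and from 854811 to 856670 (9.07-fold, centred 702 bp upstream of RPS22B). The RPL4B promoter (YDR012W) had no peak and was 1.21-fold (1.07 to 1.36) above input. The median bin outside peaks lay at 0.66-fold in the Abf1 ChIP and 0.60-fold in the Reb1 ChIP. In the Reb1 ChIP, RPL3 was 2.02-fold (1.83 to 2.22) above input and had a Reb1 peak, while the promoters of the other 5 lay between 0.45-fold and 1.03-fold.

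The factors' own genes were also compared. The REB1 promoter (YBR049C, chromosome II, 336819 to 337318) was 18.2-fold (16.9 to 19.6) above input in the Reb1 ChIP, 10.6-fold (9.43 to 11.9) with 1 read per position, and 0.89-fold (0.79 to 0.99) in the Abf1 ChIP. The ABF1 promoter (YKL112W, chromosome XI, 226070 to 226569) held no peak of either factor; it was 1.80-fold (1.63 to 1.99) above input in the Abf1 ChIP and 1.28-fold (1.14 to 1.43) in the Reb1 ChIP. REB1 was the 1 member of the 6-gene list of general regulatory factors with a peak centred in its promoter, and 0 of the 6 had an Abf1 peak there. Promoters of 1000 bp gave 1 of the 6 an Abf1 peak (0.922 by chance). With 2-fold windows 1 had Abf1 signal (0.860 by chance) and 2 had Reb1 signal (1.16 by chance).

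Proteasome genes had the highest share of promoters with a Reb1 peak among the 14 lists, 18 of 37 (48.6%, 31.9% to 65.6%), where random lists averaged 4.81 and 0 of 10000 reached 18. The strongest were the regulatory particle ATPase genes RPT5 (16.5-fold), RPT2 (10.2-fold) and RPT1 (9.65-fold) and the core particle gene PRE4 (10.2-fold). Abf1 peaks were found at 11 of the 37 (29.7%, 15.9% to 47.0%; random mean 4.16, reached by 15 of 10000 lists), including RPN4 (7.26-fold), which encodes the transcription factor that activates proteasome genes, RPN5 (7.08-fold), RPN8 (5.16-fold) and RPN1 (3.84-fold).

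Translation factor genes had peaks of both factors at 14 of 39 promoters each (35.9%, 21.2% to 52.8%). Random lists averaged 4.36 for Abf1, with 0 of 10000 reaching 14, and 5.03 for Reb1, with 1 of 10000 reaching it. Abf1 was strongest at SUI1 (14.9-fold), PAB1, which encodes the poly(A)-binding protein (8.11-fold), HCR1 (7.38-fold) and TIF1 (6.14-fold). Reb1 was strongest at TEF4 (13.2-fold), SUI1 (9.19-fold), SUP45 (7.79-fold) and PRT1 (6.28-fold). The TEF4 peak (chromosome XI, 282201 to 283260) is the same peak as that of the ribosome biogenesis gene RRP14, so it counts in both lists. In the Reb1 peak at SUI1 the Abf1 ChIP was higher, at 32.6-fold. Among the stronger peaks alone the counts were 5 for Abf1 (2.77 by chance, reached by 1416 of 10000 lists) and 6 for Reb1 (2.89 by chance, reached by 679). Aminoacyl-tRNA synthetase genes had an Abf1 peak at 7 of 20 promoters (35%, 15.4% to 59.2%; random mean 2.23, reached by 63 of 10000 lists), among them TYS1 (9.12-fold), FRS2 (4.54-fold), THS1 (2.47-fold) and GLN4 (2.25-fold), but among the stronger peaks at 2, where 1.42 were expected. Reb1 peaks were found at 3: FRS2 (12.7-fold), ILS1 (5.19-fold) and MES1 (2.01-fold). In the Abf1 peak at FRS2 the Reb1 ChIP was higher than the Abf1 ChIP, at 15.9-fold. In the Reb1 peak at MES1 the Abf1 ChIP was 2.59-fold. The Abf1 peak at GLN4 (chromosome XV, 649071 to 649250) is the same peak as that at RPS28A.

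Genes for RNA polymerases I and III had an Abf1 peak at 9 of 41 promoters (22.0%, 10.6% to 37.6%; random mean 4.61, reached by 354 of 10000 lists). Under other rules the observed count was reached by between 72 lists (stronger peaks alone, 8 against 2.92 by chance) and 883 lists (promoters of 1000 bp, 10 against 6.30). RPB8 (11.7-fold), RPC25 (6.52-fold), RET1 (4.19-fold) and RPC82 (3.58-fold) led this list. Reb1 peaks were found at 5 (random mean 5.28): RRN11 (16.8-fold), RPC19 (15.8-fold), RPA14 (14.4-fold), RRN6 (8-fold) and, named after its value was seen, RRN3. Mitochondrial ribosomal protein genes had Abf1 peaks at 9 of 69 (random mean 7.70), led by MRPS18 (16.7-fold), MRPL16 (11.5-fold), MRPL8 (11.1-fold) and MRPS12 (7.91-fold). Reb1 peaks lay at 12 of the 69 (random mean 8.97, reached by 1790 of 10000 lists; with promoters of 300 bp 12 against 6.52, reached by 246), led by MRP10 (10.4-fold), MRPL23 (9.80-fold), MRPS17 (9.45-fold) and MRPL10 (8.43-fold).

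With a promoter of 500 bp, the metabolic and DNA replication lists lay within the range of random lists. Of 22 glycolysis genes, 5 had an Abf1 peak (random mean 2.48), with HXK2 at 9.5-fold, FBA1 at 8.69-fold, PGK1 at 3.09-fold and GLK1 at 2.71-fold. The Abf1 peaks at PGK1 and GLK1 overlapped Reb1 peaks. In them the Reb1 ChIP was higher than the Abf1 ChIP, at 4.73-fold and 49.9-fold over input. In the Abf1 peaks at HXK2 and FBA1 the Reb1 ChIP was 0.449-fold and 1.04-fold. Under 3 wider rules (promoters of 1000 bp, 2-fold windows, any base of a peak) 8 of the 22 had Abf1 signal, reached by 102, 85 and 131 of 10000 lists. Reb1 peaks were found at 4 (random mean 2.82): GLK1 (16.1-fold), GCR2 (4.58-fold), TPI1 (4.10-fold) and GCR1 (3.8-fold). Of 36 respiratory chain genes, 7 had an Abf1 peak (random mean 4.01), led by QCR9 (9.73-fold), ATP18 (8.96-fold), COX6 (8.36-fold) and CYC1 (5.54-fold). The same wider rules gave 11, 10 and 11 of the 36, reached by 158, 252 and 135 of 10000 lists, so these Abf1 results depend on the promoter rule. Reb1 peaks lay at 5 of the 36 (random mean 4.67), led by ATP4 (12.2-fold), COR1 (10.3-fold), NDI1 (10.2-fold) and ATP18 (8.64-fold). In the Reb1 peak at ATP18 the Abf1 ChIP was higher, at 12.4-fold. DNA replication genes had Abf1 peaks at 2 of 46 (POL31, 3.21-fold, and MCM3, 2.21-fold; random mean 5.11, with 1002 of 10000 lists at 2 or fewer). With any base of a peak in the promoter these were 2 against 6.94 by chance (218 lists as low), and with 2-fold windows 2 against 6.59 (296 lists), so this result too depends on the promoter rule. The same list had Reb1 peaks at 7 (random mean 5.95), led by CDC6 (10.5-fold), CDC9 (7.25-fold), RNR1 (6.85-fold) and POL2 (6.70-fold).

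Inducible genes had fewer peaks than the random mean, within the range of random lists. Of 15 galactose and phosphate genes, PHO8 had an Abf1 peak, which was 1.04-fold over input, and 0 had a Reb1 peak (0% to 21.8%); random means were 1.7 and 1.94, with 4794 and 1263 of 10000 lists at or below these counts. Of 32 stress response genes, SOD1 (5.42-fold) and TSL1 (1.36-fold) had an Abf1 peak (random mean 3.57, with 2897 of 10000 lists at 2 or fewer) and TPS1 (2.78-fold) had a Reb1 peak (3.13%, 0.0791% to 16.2%; random mean 4.15, with 667 of 10000 lists at 1 or fewer).

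**Figure D4:**
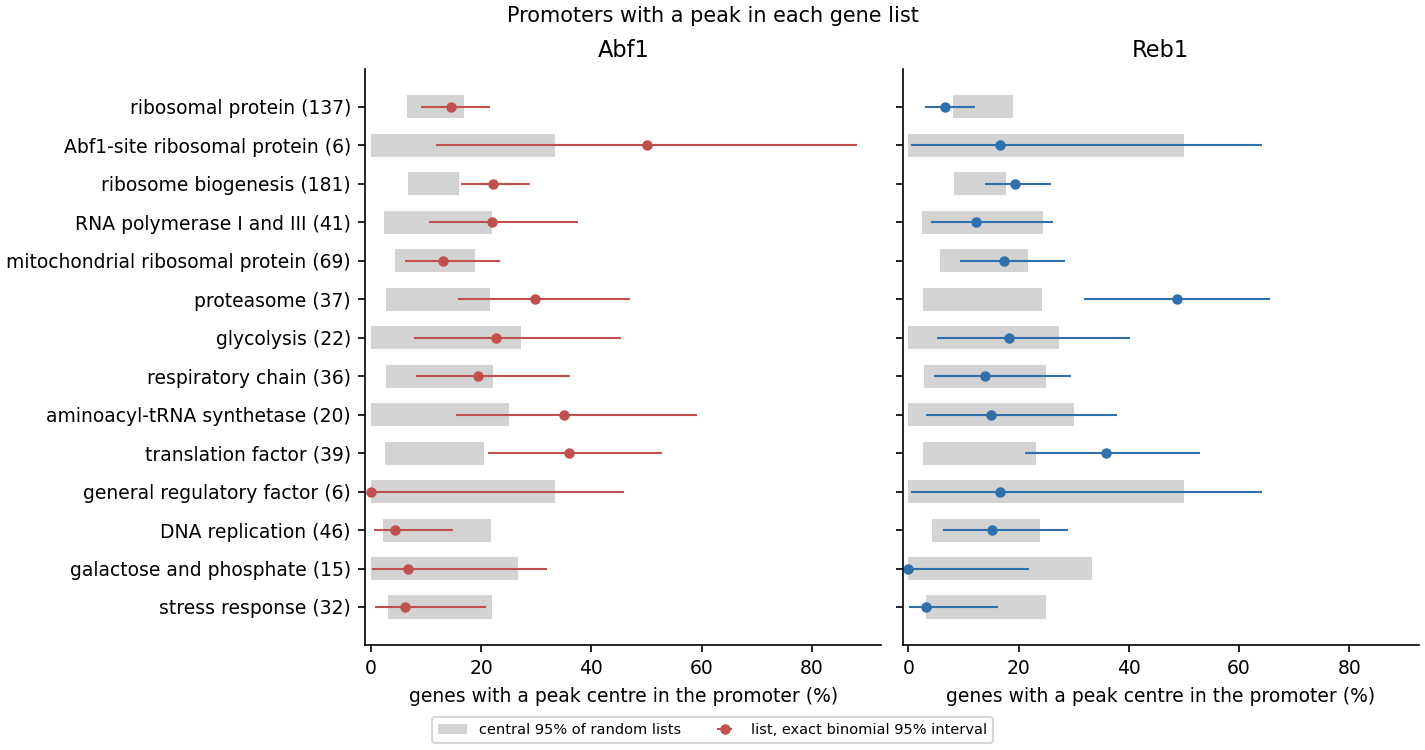
Share of genes with a peak centre in the promoter (horizontal, %) for the 14 gene lists (vertical, list size in brackets) and each factor, with exact binomial 95% intervals; grey bars span the central 95% of 10000 random lists of the same size. Proteasome genes in the Reb1 panel reach 48.6% and ribosomal protein genes 6.57%.

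Features outside coding gene promoters were examined in all libraries. The median coding sequence was at a log2 ratio of -0.56 in the Abf1 ChIP (n = 5895) and -0.74 in the Reb1 ChIP (n = 5898); with the median bin outside peaks set to 1 these became 0.04 and -0.0038. tRNA genes lay above it in both ChIPs, with medians of 0.58 (0.51 to 0.63, n = 272) for Abf1 and 0.59 (0.50 to 0.71, n = 273) for Reb1, or 1.18 and 1.32 on the second scale. Small nucleolar RNA genes had medians of 0.15 (0.042 to 0.31) and 0.48 (-0.10 to 0.71; n = 76 each), or 0.75 and 1.22 on the second scale. Coding sequences of the 137 ribosomal protein genes had medians of 0.11 (0.059 to 0.19) for Abf1 and -0.20 (-0.26 to -0.13) for Reb1, or 0.72 and 0.54 on the second scale. For glycolysis genes the medians were -0.12 and -0.50 (0.48 and 0.24 on the second scale), and for galactose and phosphate genes, which are little transcribed in rich medium, -0.77 and -0.85 (-0.17 and -0.12).

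At the ribosomal DNA, where reads from the repeated copies are placed on the assembly's few copies or are missing, Reb1 was enriched. The spacer between RDN5-1 and RDN25-2 (chromosome XII, 459797 to 460922) held 149631 Reb1 ChIP reads, 2.51-fold over input (2.49 to 2.53), and the Abf1 ChIP was 1.01-fold (0.992 to 1.02). Under this scaling the median bin outside peaks lay at 0.66-fold for Abf1 and 0.60-fold for Reb1, so 1.01-fold does not mean absence of Abf1 signal. In the 2 kb after the last annotated ribosomal RNA gene, RDN5-6 (489470 to 491469), the Reb1 ChIP was 25.8-fold (24.5 to 27.1) over input, 9.42-fold (8.68 to 10.2) with 1 read per position, and the Abf1 ChIP was 0.826-fold (0.761 to 0.895).

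Chromosome ends were enriched in both ChIPs. Within 1 kb of the outermost read of a chromosome there were 26 Abf1 peaks at 19 of 32 ends and 26 Reb1 peaks at 24 of 32 ends. This was 2.78% and 3.11% of the peaks in 0.266% of the sequence. Median ChIP over input in these peaks was 3.89-fold (2.75 to 5.14) for Abf1 and 14.9-fold (12.5 to 21.8) for Reb1, and 4.12-fold and 13.2-fold with 1 read per position. Most were shared, 22 of the 26 Abf1 and 20 of the 26 Reb1 peaks.

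**Figure D5:**
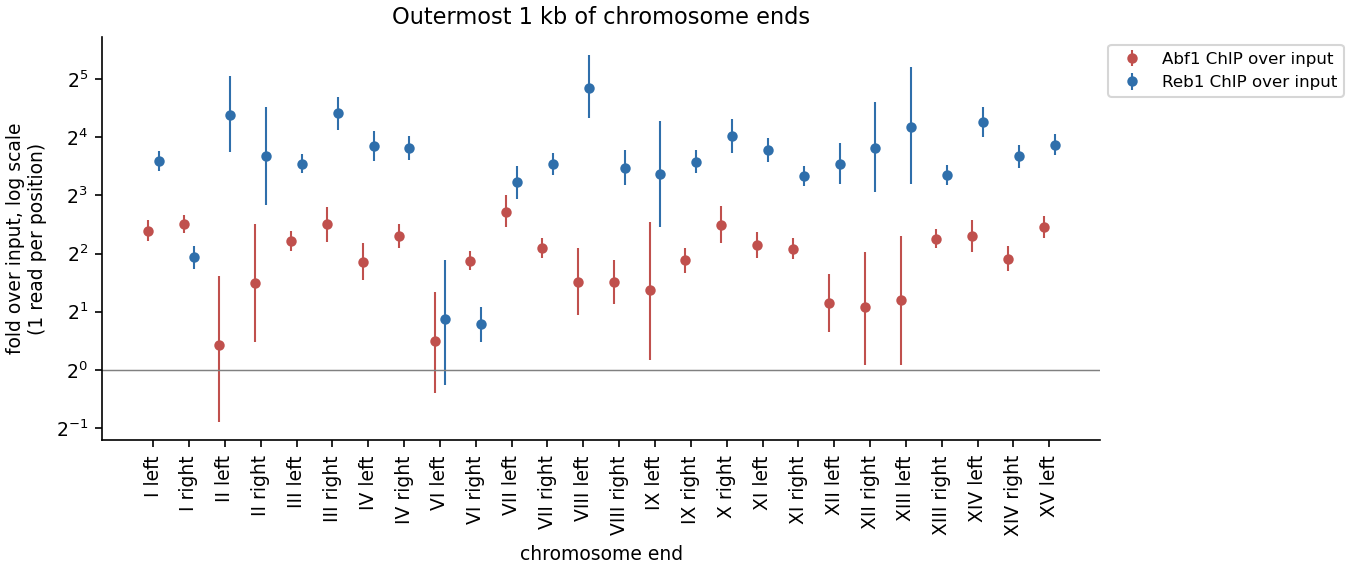
Fold over input with 1 read per position (vertical, log scale) in the outermost 1 kb of the 26 chromosome ends with at least 10 input positions in both inputs (horizontal), for Abf1 and Reb1, with exact conditional binomial 95% intervals. The median end is at 4.00-fold for Abf1 and 12.4-fold for Reb1.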

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

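The tests in this part were chosen only after the reads had been seen, and no biological explanation was tested. LEU2 and URA3, auxotrophic marker genes that are deleted in many laboratory strains, were almost free of input reads but held ChIP reads. LEU2 (chromosome III, 91324 to 92418) had 114 reads in the Abf1 ChIP and 63 in the Reb1 ChIP, against 12 and 7 in the inputs. URA3 (chromosome V, 116167 to 116970) had 175 and 230, against 1 and 0. The ChIP reads amounted to 15.6% and 11.0% of the median gene at LEU2 and to 32.6% and 54.7% at URA3.

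Genomic DNA of a yeast strain with intact LEU2, URA3 and MET17 could have entered the ChIP libraries. It would have brought reads of MET17, expected at 37.8 distinct positions in the Abf1 ChIP and 12.2 in the Reb1 ChIP, but MET17 had 0 reads in both, which argues against such a strain. A few molecules amplified many times could also give such counts, but the reads started at 31 and 45 distinct positions in the Abf1 ChIP and at 10 and 22 in the Reb1 ChIP (LEU2 and URA3). With 1 read per position the lower bounds of ChIP over input were at least 4.10-fold for Abf1 and 4.43-fold for Reb1, which argues against this explanation. Reads of plasmids or of another library on the same lane were not tested.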

How the results depend on the processing

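Joined regions, regions away from chromosome ends and the peak summit were chosen as alternatives only after the data had been seen; the others were planned. Of 69 alternative values, 41 stayed close, which for counts means within 1.5 times and for medians and shares inside the 95% interval of the reported value. The other 28 moved, and no median changed sign. No paired analysis was possible because each group has 1 library. With the median bin outside peaks set to 1, the log2 medians rose to 1.91 in Abf1 peaks, 3.23 in Reb1 peaks, and 1.18 (Abf1) and 1.32 (Reb1) at tRNA genes. Unshifted reads gave 1.10, 2.25, 0.27 and 0.39 in the same order. At tRNA genes, 1 read per position gave 0.70 and 0.81, and the other strain's input 0.84 and 0.40. With 1 read per position the median coding sequence rose too, from -0.56 to -0.25 (Abf1) and from -0.74 to -0.48 (Reb1). More than 1 kb from a peak, tRNA genes then exceeded coding sequences by 0.93 (Abf1) and 1.30 (Reb1), against 1.09 and 1.31 with all reads. The excess over coding sequences thus did not grow.

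The stronger 50% of each peak list left 80 shared Abf1 peaks and raised the promoter shares to 64.1% (Abf1) and 79.1% (Reb1). With fewer peaks, ribosome biogenesis promoters fell to 24 (Abf1, 12.9 by chance) and 21 (Reb1, 13.4 by chance). Both stayed above the random mean, and 22 and 251 of 10000 lists reached these counts, uncorrected for the number of comparisons. Ribosomal protein promoters fell to 3 (Abf1, 9.75 by chance; 85 of 10000 lists as low, where the full list lay above the random mean) and 5 (Reb1, 10.2 by chance; 513 of 10000 lists as low, against 107 before). Overlap of at least 50% of both peaks left 55 shared peaks, and centres within 100 bp left 83. Promoters of 300 bp gave shares of 41.9% and 58.3%, promoters of 1000 bp 66.9% and 79.4%, and joined regions 65.9% and 75.5%. With 2-fold windows of 200 bp in place of peaks, 14 ribosomal protein promoters had Reb1 signal where 26.5 were expected (35 of 10000 lists as low), and 18 had Abf1 signal, below the 19.6 expected.

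The stronger 50% was not applied to the medians in peaks, as it selects on the same ratio, and motif alternatives were not run without a genome sequence.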

Other observations

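The counts of promoters with both peaks, the tests at chromosome ends and the interval on the tRNA correlation were chosen only after the results had been seen. The tests of neighbouring peaks and of shared tRNA signal were set before their values were computed.

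Promoters that held peak centres of both factors were counted per list, beside the count that independent placement at the same rates gives. No test was made. A wide peak that reaches a promoter from a centre elsewhere was not counted. RPC19 thus counted for Reb1 alone: the Abf1 ChIP was 21.3-fold over input in the Reb1 peak of its promoter, but the overlapping Abf1 peak was centred in the gene. Of the 181 ribosome biogenesis promoters, 72 had a peak of either factor and 3 had both (7.73 if independent), and of the 37 proteasome promoters 26 had either and 3 both (5.35). Both peaks were found at 0 promoters of RNA polymerase I and III genes (1.10), 1 each of ribosomal protein (1.31), mitochondrial ribosomal protein (1.57), glycolysis (0.909) and DNA replication genes (0.304), 2 each of respiratory chain (0.972) and aminoacyl-tRNA synthetase genes (1.1), 5 of translation factors (5.03) and 111 of all genes (86.6). The counts per list are small, and whether the lists differ was not tested.

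Chromosome ends were enriched in both ChIPs, by a median of 4.00-fold for Abf1 and 12.4-fold for Reb1 over 26 ends with 1 read per position. Few input reads could raise such ratios, but over the outermost 1 kb of all ends, with or without a peak, 200 bp windows exceeded windows elsewhere with the same input by a median log2 difference of 2.06 (1.51 to 2.53) for Abf1 and 4.05 (3.12 to 4.69) for Reb1, which argues against this explanation for the 111 (Abf1) and 98 (Reb1) of 160 windows that could be matched. Repeated amplification of few ends would bring the ratio with 1 read per position to input level. The log2 median over all 32 ends was 1.89 (1.38 to 2.25) for Abf1 and 3.66 (3.50 to 3.87) for Reb1. The pseudocount raises these values where counts are few: the right end of chromosome V, with 0 Reb1 ChIP positions, still had 1.17. The 26 ends with at least 10 input positions, at 4.00-fold and 12.4-fold without a pseudocount, argue against this explanation for those ends. A signal that does not depend on the factor would tend to rank the ends alike in both ChIPs; rho was -0.0092 (-0.43 to 0.43), an interval too wide to decide. At 17 of the 26 ends both lower bounds lay above 2-fold, and 0 ends had the lower bound of either factor above 4-fold and the upper bound of the other below 2-fold.

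tRNA genes lay above input in both ChIPs. Spread from neighbouring called peaks could contribute, but tRNA genes more than 1 kb from a peak still exceeded coding sequences equally far away by a log2 difference of 1.09 for Abf1 and 1.31 for Reb1, which argues against it. A signal that does not depend on the factor, as at highly transcribed genes, might raise the same tRNA genes in both ChIPs. Across 164 such genes rho was 0.10 (-0.05 to 0.24), against 0.31 for coding sequences, and 0.15 with 1 read per position, at the edge of the central 95% of shuffled values for all reads (-0.15 to 0.15). The limits set beforehand were above 0.3 for such a signal and at or below 0.1 against it. With all reads the value, 0.0995, narrowly met the limit against such a signal. With 1 read per position it lay above that limit. The interval for all reads, added later, excludes a rho above 0.3, but a signal that raised nearly all tRNA genes alike (245 of 272 lay above input for Abf1 and 225 of 273 for Reb1) would leave no such correlation, so this form stays open. Without an untagged strain, the part of the signal at tRNA genes and chromosome ends owed to the purification itself could not be measured.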
